A study of Mus musculus with 30 samples.

How the data were processed

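RNA was sequenced from microglia of C57BL/6 mice in 8 groups: naive mice and mice with experimental autoimmune encephalomyelitis (EAE) that were wild type (WT), lacked Atg7 in Cx3cr1-expressing cells (KO) or were old, sampled without EAE or at day 21 or 35 after induction. Per the labels' protocols, KO mice were Atg7fl/fl Cx3cr1CreERT and WT mice Atg7wt/wt Cx3cr1CreERT2, and they received 3 doses of 4 mg tamoxifen 48 h apart, at least 18 days before EAE. EAE was induced with rmMOG (residues 1 to 125) and pertussis toxin. Cells were sorted as live CD11b+ CD45int Ly6G− and/or eYFP+, and female and male samples were pooled 1:1. Libraries were made with the SMARTer Stranded Total RNA-Seq Pico kit. The labels give age only as young or old. They do not state the Cre status of the old mice, the deleted Atg7 exon, the EAE scale, or whether the replicates of a group come from separate mice and separate sorts, so the replicates are treated as independent without a source for it.

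The deposited count table holds raw counts per Ensembl gene for 46078 genes, which the authors made with CASAVA, bcl2fastq and STAR on build GRCm38, per the submitters' processing notes. Tool versions, the read counter, its strand setting and the annotation release are not given in the sources used here. The EAE score and the RNA integrity number of each library are scores in a second deposited table, per the file headers. Every value of the columns used was checked to be a whole number of at least 0. Of 32 count columns 30 were used. Column names are not sample titles, and the authors' sample table gives a group and a plate well for each. They were joined to the samples by counting wells down the plate's columns, an inference by which 30 of 30 title numbers pointed to a column of the title's group, against 2 when wells were counted along the other axis. For 1 library, replicate 3 of day 35 WT, the title gives wild type while the knockout status gives KO, and it was kept as WT. Replicate numbers are accession order. Symbols and coordinates came from GENCODE M21 (Ensembl 96, GRCm38) and covered 45143 genes (98%). The 935 genes without a symbol held 0.0552% of the counts, and 112 genes that share a symbol were kept by identifier.

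Counting error alone sets a floor of 3 counts per group total. Where a group had no count of a gene, a fold is given as at least the ratio to that floor. Where it had 1 to 3, the count ratio is given with its 95% interval. These intervals, and the Wilson intervals given for shares of a library, cover counting error only.

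Genes were filtered with filterByExpr (minimum count 10, minimum total 15), leaving 13880, and scaled by TMM. A model with 1 mean per group and 22 residual degrees of freedom was fitted to all 30 libraries with edgeR 4.0.16 (glmQLFit with robust=TRUE) in R 4.3.3, and 16 contrasts were tested with the quasi-likelihood F test. P-values were adjusted over genes within each contrast by the method of Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called. The interaction contrasts are differences of differences. Log2 fold changes (log2FC) are given with their standard error (SE). Levels in CPM (counts scaled to a common library total, with TMM factors) are group means with the standard deviation between libraries. Principal components used log2 CPM with a prior count of 2.

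Camera (limma 3.58.1, inter-gene correlation preset to 0.01) was run per contrast over 30 gene lists, 19 of processes and 11 of cell markers, written down before the data were examined, with adjustment over the lists. The same test with an estimated correlation and fry were the alternatives. List member counts are for the adjustment over all genes and, where stated, over the list alone. A further list of Xist and Y-linked genes was used once as a check of sex. The markers come from general knowledge of the cell types and not from these libraries.

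Genes to be named were also fixed before the data were examined: Atg7 throughout, then the 6 highest and 6 lowest by log2FC for the KO against WT, WT EAE against naive and old against young comparisons, and 4 each way for the others. They had to have an adjusted p under 0.05, at least 5 CPM in the higher group, every library of one group above every library of the other, and no predicted or clone-type name. Some genes that the rule selects are not reported here. The rule on every library cannot be applied to an interaction and was left out there. Of a list, up to 4 members with the lowest adjusted p are named, and of a marker list up to 2 with the highest mean.

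EAE scores and single quality measures were compared by exact permutation of libraries, two-sided, with adjustment over the measures tested. The overlaps of KO and age effects share WT libraries, so they were set against 20 simulated data sets with unchanged groups sharing a control and against splits of the control. Libraries apart from their group were sought with the Dixon test in each group.

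The pipeline was tested on simulated data with 200 genes changed. It recovered 61.2 to 92.6% of 4-fold and 28.9 to 72.6% of 2-fold changes, and at most 6.58% of its calls were false.

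The alternatives were RLE scaling, DESeq2 1.42.0, no filter and a stricter one (2 CPM in 4 libraries), a fit of only the groups compared, a block for the i5 library index, replicate 3 of day 35 WT moved to KO, every library left out in turn, and a fold threshold of 1 on the log2 scale. The groups, comparisons, tests, filters and these alternatives were chosen before the data were examined. Added after the data were seen were a fit without 3 libraries far from their group, a neutrophil marker covariate, a sex covariate and those for the overlap of day 35 KO with naive age. Tables were made with jsonlite 2.0.0, and figures with Python 3.11.15 and matplotlib 3.10.9. Raw reads were not analysed here.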

Results

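RNA was sequenced from 30 libraries of sorted mouse microglia, the resident macrophages of the central nervous system. There were 4 naive libraries each of wild-type mice (WT), mice lacking Atg7 in Cx3cr1-expressing cells (KO) and old mice. At day 21 of experimental autoimmune encephalomyelitis (EAE), an induced neuroinflammation, there were 3 WT and 4 KO libraries. At day 35 there were 4 WT, 4 KO and 3 old libraries. Total counts per library ran from 4712803 to 11034565 with a median of 6769302. Libraries are named by group and replicate, as in day 21 WT 2.

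**Figure D1:**
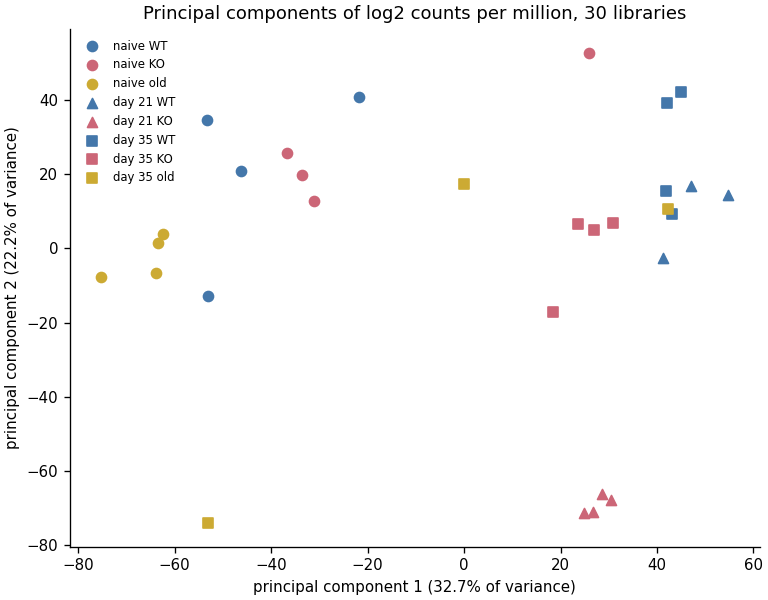
Each point is 1 of the 30 libraries on the first principal components of log2 CPM, which hold 32.7% and 22.2% of the variance; colour gives WT, KO or old and shape gives naive, day 21 or day 35. Day 35 old 1 lies 99.9 units from the centre of its group, naive KO 4 lies 65.6 and naive WT 3 lies 40.8.

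Atg7 (ENSMUSG00000030314, chromosome 6, 114643097 to 114860614 on GRCm38), the enzyme that activates the ubiquitin-like proteins of autophagy, was the targeted gene. Its level was 20.2 ± 8.62 CPM in naive KO and 31.6 ± 6.32 in naive WT (mean ± SD, n = 4 each), 32.8 ± 2.73 in KO and 23.2 ± 3.02 in WT at day 21 (n = 4 and 3), and 32.5 ± 1.54 and 22.6 ± 1.41 at day 35 (n = 4 each). Atg7 did not pass the edgeR test between KO and WT at any of these times (log2FC −0.65, SE 0.3, adjusted p = 0.516 in naive mice; log2FC 0.50, SE 0.325, adjusted p = 0.303 at day 21; log2FC 0.53, SE 0.299, adjusted p = 0.338 at day 35). Only the fits restricted to the groups compared put Atg7 past the threshold in these comparisons, with log2FC 0.48 at day 21 and 0.54 at day 35. A count per gene cannot show the loss of single exons. Camera called neither the core autophagy genes nor the autophagy receptors between KO and WT (adjusted p = 0.512 and 0.512 in naive mice, 0.574 and 0.552 at day 21, 0.849 and 0.734 at day 35). Xist, which is transcribed from the inactive X chromosome, ran from 58.93 CPM in day 35 WT 3 to 2042 in day 21 WT 3, and 4 Y-linked genes summed to between 4.988 CPM in day 35 old 2 and 217.9 in day 21 KO 4, so the pools were not even in sex.

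**Figure D2:**
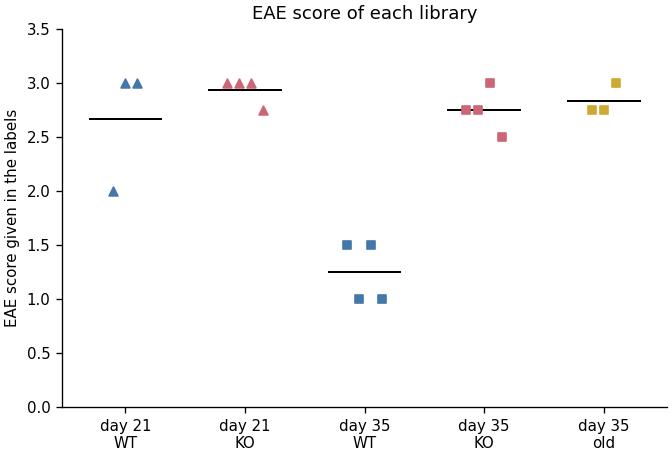
Points are the EAE score of each library (vertical axis, as given in the labels) in the 5 EAE groups, and lines are group means. The scores of day 35 KO lie between 2.5 and 3 and those of day 35 WT between 1 and 1.5.

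The EAE score was 2.75 ± 0.204 in day 35 KO and 1.25 ± 0.289 in day 35 WT (mean ± SD, n = 4 each; exact permutation test, two-sided, p = 0.0286, the smallest this design allows; adjusted p = 0.0477 over 5 comparisons). Old mice scored 2.83 ± 0.144 at day 35 (n = 3; exact permutation p = 0.0286, adjusted p = 0.0477, against WT). At day 21 the scores were 2.94 ± 0.125 in KO (n = 4) and 2.67 ± 0.577 in WT (n = 3), a difference within the spread between libraries (exact permutation p = 0.714, adjusted p = 0.714). WT scores fell between day 21 and day 35 (exact permutation p = 0.0286, adjusted p = 0.0477), while those of KO did not pass the test (exact permutation p = 0.371, adjusted p = 0.464). The share of counts from mitochondrial genes was 8.77 ± 0.339% in day 21 KO and 7.55 ± 0.997% in WT, 7.98 ± 0.782% in day 35 KO, 8.26 ± 0.827% in day 35 old and 5.33 ± 0.736% in day 35 WT (exact permutation p = 0.0286 and adjusted p = 0.049 for each against WT of the same day).

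**Figure D3:**
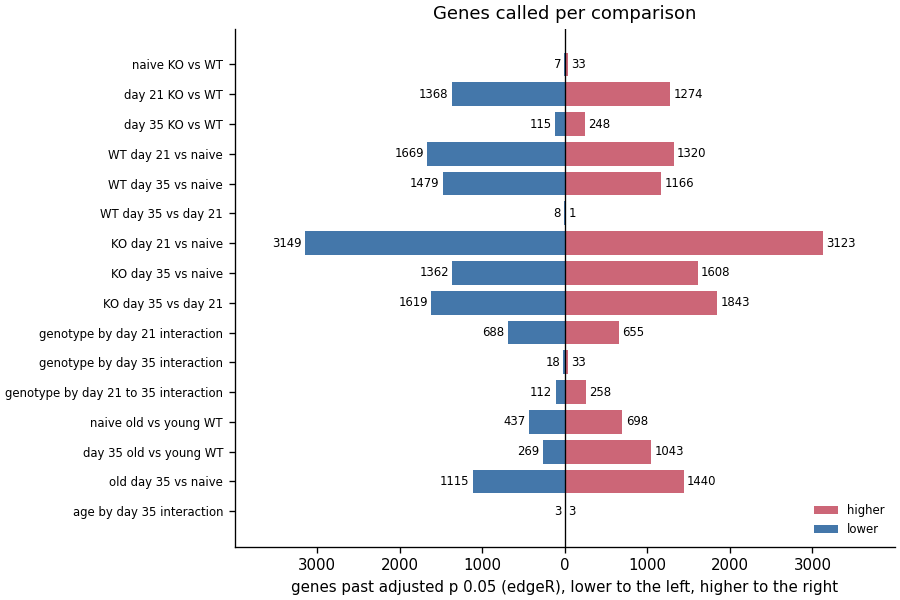
Bars are the genes past an adjusted p of 0.05 in edgeR for each of the 16 comparisons, lower to the left and higher to the right. KO at day 21 against naive has the most (3123 higher, 3149 lower), and the age by day 35 interaction the fewest (3 higher, 3 lower).

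The comparison of naive KO with naive WT (n = 4 each) shows how KO differed without EAE. Pianp, a membrane protein that binds paired immune receptors, rose from 1.09 ± 1.21 to 24.5 ± 2.21 CPM (log2FC 4.47, SE 0.892, adjusted p = 0.0291). Cdkn1a, the cell-cycle inhibitor p21, rose (log2FC 1.75, SE 0.244, adjusted p = 0.000373). So did the polarity scaffold Dlg5 (log2FC 2.06, SE 0.332), the secreted protease Htra3 (log2FC 1.79, SE 0.208), the sulfotransferase Chst1 (log2FC 1.34, SE 0.207) and the ubiquitin ligase Neurl1b (log2FC 1.18, SE 0.235). Cx3cr1, the fractalkine receptor and the locus of the Cre allele (chromosome 9, 119901616 to 120069879), fell from 2574 ± 1150 to 168.8 ± 82.2 CPM (log2FC −3.93, SE 0.491, adjusted p = 0.000312). The ubiquitin ligase Mid1 (log2FC −1.28, SE 0.27), the adhesion receptor Adgrl2 (log2FC −0.94, SE 0.169) and the chemokine Ccl9 (log2FC −0.79, SE 0.163) were also lower.

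Gene lists were tested with camera, with its adjusted p given first for a preset correlation between genes and then, marked estimated, for that correlation estimated from the data. Of the MHC class I genes, which present antigen to CD8 T cells, 1 of 17 rose (8 adjusted over the list alone, camera adjusted p = 5.13e-11, 0.396 estimated), namely H2-M3 (log2FC 0.65, SE 0.146, adjusted p = 0.0419). No MHC class II gene passed over all genes (5 over the list alone, camera adjusted p = 0.0135, 0.802 estimated). Camera called 4 marker lists lower in KO with no member called by edgeR: neutrophil (adjusted p = 9.12e-05), monocyte (0.0135), border macrophage (0.0276) and erythroid (0.0276), each with 0.802 estimated. Summed neutrophil markers were 2389 ± 1170 CPM in KO and 9102 ± 6100 in WT (exact permutation p = 0.114, adjusted p = 0.171). edgeR called 40 genes (33 higher, 7 lower; 1293 at an unadjusted p under 0.05). The count was 11 without naive KO 3, 12 without naive KO 2, 14 without naive WT 4, 17 without naive WT 2, 21 without naive KO 1 and 69 without naive KO 4. Camera lost the lists MHC class II without naive KO 2 or 3 (up to 0.341), monocyte without naive KO 4 or naive WT 3 (up to 0.52), border macrophage without naive KO 4 or naive WT 1 (up to 0.752), neutrophil without naive KO 4 (up to 0.0579) and erythroid without naive KO 3 or naive WT 2 or 3 (up to 0.295), adjusted p in brackets. edgeR lost Pianp without any library but naive KO 4 or naive WT 3 (log2FC 4.06 to 5.72). Neurl1b lost its call without any library but naive KO 4 or naive WT 1 or 3 (1.07 to 1.37), and Mid1 without any library but naive WT 3 (−1.38 to −1.20). Adgrl2 lost its call without naive KO 3 (−1.16 to −0.80), and Ccl9 without any library but naive KO 4 or naive WT 1 or 3 (−0.88 to −0.65). H2-M3 lost its call without any library but naive KO 1 or 4 or naive WT 3 (0.53 to 0.77).

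At day 21, KO (n = 4) was compared with WT (n = 3). Homeostatic microglia genes fell in KO, 19 of 24 of them (21 over the list alone, camera adjusted p = 2.67e-13, 0.235 estimated). Among them were the purinergic receptor P2ry12, at 349 ± 20.5 CPM in KO and 1281 ± 133 in WT (log2FC −1.88, SE 0.255, adjusted p = 1.66e-05), and the receptor Gpr34 (log2FC −2.39, SE 0.244). Type I interferon response genes rose, 19 of 32 (25 over the list alone, camera adjusted p = 2.62e-11, 0.222 estimated). They included the signal transducer Stat2 (log2FC 1.10, SE 0.158). Cell cycle genes rose, 20 of 32 (30 over the list alone, camera adjusted p = 4.95e-12, 0.286 estimated). Among them was the replication helicase subunit Mcm5 (log2FC 1.58, SE 0.382). Of cytokine and chemokine genes 8 of 25 rose and 1 fell (10 over the list alone, camera adjusted p = 0.00628, 0.521 estimated). The nitric oxide synthase Nos2 (log2FC 4.21, SE 0.937) rose.

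Monocyte markers rose in the same libraries, 6 of 12 (12 over the list alone, camera adjusted p = 1.28e-06, 0.286 estimated). The calcium-binding S100a4 rose 102.7-fold, 95% interval 18.1 to 4090. Fn1, the most abundant of them, stood at 2085 ± 267 CPM in KO and 283 ± 131 in WT, and their sum at 2734 ± 343 and 407 ± 159 (exact permutation p = 0.0286, adjusted p = 0.0572). Border macrophage markers rose, 5 of 10 (8 over the list alone, camera adjusted p = 1.36e-05, 0.235 estimated). T and NK cell markers rose too, 8 of 10 (9 over the list alone, camera adjusted p = 1.28e-06, 0.126 estimated). The T cell receptor subunit Cd3e rose 44.9-fold, 95% interval 12.1 to 376.3. B and plasma cell markers fell, 3 of 5 (3 over the list alone, camera adjusted p = 0.00243, 0.0792 estimated). Erythroid markers fell as well, 5 of 5 (5 over the list alone, camera adjusted p = 0.000101, 0.222 estimated). Summed neutrophil markers were 570.4 ± 54.3 CPM in KO and 719 ± 13.2 in WT. The genes that rose furthest were Ms4a8a, a membrane protein (62.8-fold, 95% interval 17.1 to 524), the aspartic protease Napsa (log2FC 5.58, SE 1.51), Slfn4 (log2FC 5.55, SE 1.83) and Gpr141 (5.46, SE 1.62), the monocyte surface antigen Ly6c2 (log2FC 5.16, SE 1.53) and the arginase Arg1 (log2FC 5.04, SE 1.47). Those that fell furthest were the globins Hbb-bt (81.8-fold, 95% interval 22.2 to 681.4) and Hbb-bs (log2FC −3.81, SE 0.924) and Hba-a1 (−3.29, SE 0.909), the synaptic protein Cplx2 (log2FC −3.93, SE 1.27), the adenylate cyclase Adcy8 (log2FC −3.40, SE 0.464) and the kinase Camk2a (log2FC −3.29, SE 0.765). edgeR called 2642 genes (1274 higher, 1368 lower). The count was 1358 without day 21 WT 3 and 1526 without day 21 WT 2. Ms4a8a lost its call without day 21 WT 2 or 3. Napsa, Gpr141, Ly6c2 and Arg1 lost their calls without day 21 WT 2 or 3 (log2FC 4.44 to 7.48), and Slfn4 without any library but day 21 KO 3 (log2FC 5.31 to 6.21). Cplx2 lost its call without any library but day 21 KO 1 or day 21 WT 1 (log2FC −4.85 to −3.40), and Hba-a1 without day 21 WT 3 (log2FC −3.68 to −2.75).

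**Figure D4:**
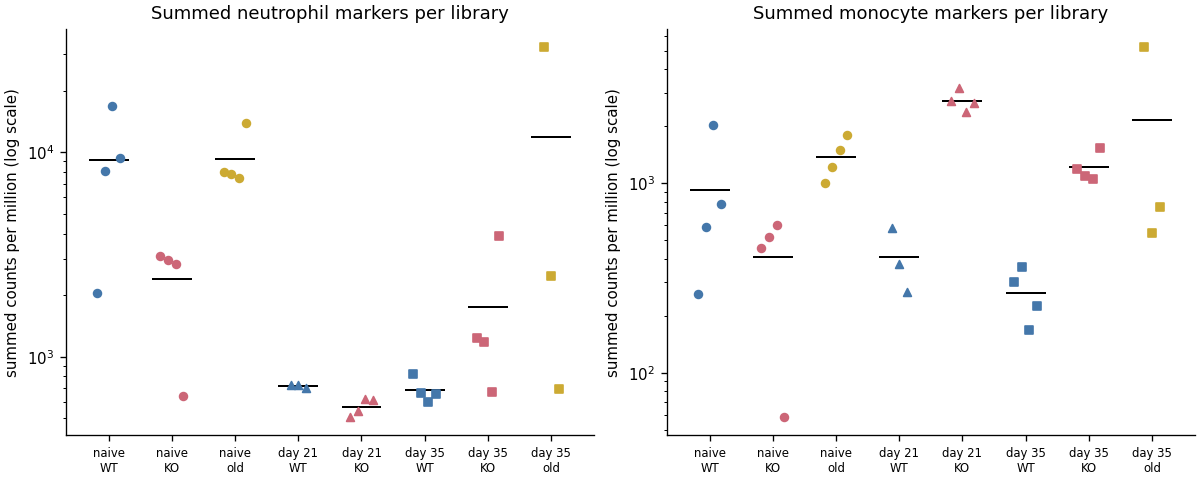
Points are the summed CPM (log scale) of 14 neutrophil markers and 12 monocyte markers in each library, by group, and lines are group means. Monocyte marker sums were 2734 ± 343 in day 21 KO and 406.6 ± 159 in day 21 WT (mean ± SD), and the neutrophil sum of day 35 old 1 was 32470.

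At day 35 KO and WT (n = 4 each) were compared after the WT scores had fallen. Genes of disease-associated microglia rose in KO, 11 of 27 (22 over the list alone, camera adjusted p = 5.94e-17, 0.124 estimated). Apoe was at 24820 ± 9360 CPM in KO and 5343 ± 1870 in WT (log2FC 2.22, SE 0.525, adjusted p = 0.0304), the lipoprotein lipase Lpl at 228 ± 46.8 and 55.0 ± 12 (log2FC 2.05, SE 0.267, adjusted p = 0.000218), and the growth factor Igf1 at 67.5 ± 13.6 and 8.77 ± 2.51 (log2FC 2.94, SE 0.404, adjusted p = 0.000375). The cytokine Csf1 (log2FC 1.18, SE 0.226) rose as well. Of cholesterol export genes 5 of 16 rose (7 over the list alone, camera adjusted p = 3.33e-05, 0.239 estimated). They included Apoc1 (log2FC 3.23, SE 0.545). Of lipid droplet and fatty acid genes 2 of 20 rose (4 over the list alone, camera adjusted p = 2.81e-05, 0.101 estimated). Lpl belongs to each of these lists. No homeostatic gene was called though camera called the list lower (0 over the list alone, camera adjusted p = 4.97e-05, 0.485 estimated). Of cytokine and chemokine genes 7 of 25 rose (14 over the list alone, camera adjusted p = 1.06e-06, 0.239 estimated). Of interferon response genes 3 of 32 rose (11 over the list alone, camera adjusted p = 1.97e-06, 0.319 estimated).

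Neutrophil markers rose in the same libraries, 5 of 14 (11 over the list alone, camera adjusted p = 4.74e-08, 0.239 estimated). They were the granule and antimicrobial proteins S100a8 (log2FC 6.50, SE 1.53, adjusted p = 0.0304) and S100a9 (5.63, SE 1.4), Ltf (5.64, SE 1.45), Lcn2 (5.55, SE 1.47) and Ngp (5.34, SE 1.45). The 14 markers summed to 1740 ± 1440 CPM in KO and 686 ± 92.5 in WT (exact permutation p = 0.0571, adjusted p = 0.0979). The sort (CD45int Ly6G− and/or eYFP+) does not show a gate against Ly6G, a neutrophil protein, for every library. Summed monocyte markers were 1220 ± 224 and 265 ± 84.5 CPM (exact permutation p = 0.0286, adjusted p = 0.0572) with no member called (1 over the list alone, camera adjusted p = 0.00394, 0.486 estimated). Camera also called astrocyte, oligodendrocyte, neuron and erythroid markers higher (adjusted p = 5.52e-05, 0.00106, 0.00113 and 0.000218; 0.239, 0.319, 0.422 and 0.239 estimated). Of their members edgeR called only Hbb-bt (log2FC 2.51, SE 0.668). Their sums were 437 ± 90, 262 ± 110, 93.9 ± 77.3 and 119.7 ± 67.6 CPM in KO and 281 ± 68.8, 151.5 ± 73.3, 35.6 ± 28.6 and 24.2 ± 14.9 in WT. The apolipoprotein Apoc4 (log2FC 4.65, SE 0.936) rose, and the genes that fell furthest were the orphan receptor Gpr165 (log2FC −1.85, SE 0.487), the semaphorin Sema6d (log2FC −1.47, SE 0.371), Tmem204 (log2FC −1.26, SE 0.304), the basement membrane protein Nid2 (log2FC −1.20, SE 0.248), the potassium channel Kcnk12 (log2FC −1.14, SE 0.285) and Tmc7 (log2FC −0.93, SE 0.221). edgeR called 363 genes (248 higher, 115 lower). The count was 53 without day 35 WT 2, 63 without day 35 KO 3, 93 without day 35 WT 1, 100 higher and 28 lower without day 35 WT 4, 119 higher and 35 lower without day 35 KO 2, 161 without day 35 KO 1 and 1.7e+02 (43 lower) without day 35 KO 4, and 777 without day 35 old 1, which is in neither group (14296 genes tested, against 13880). With day 35 WT 3, whose title and knockout status disagree, moved to KO, 80 were higher and 90 lower, 97 of them shared with the 363. Camera lost the monocyte list without day 35 KO 4 or day 35 WT 3 (adjusted p up to 0.0975) and the neuron list without day 35 KO 4 (0.091). The edgeR call was lost for S100a8 without any library but day 35 KO 1, 2 or 3 (log2FC 4.88 to 7.24). S100a9, Ltf, Lcn2 and Ngp lost their calls without any of the 8 libraries (3.71 to 6.14), and Apoc4 without day 35 KO 3 (3.98 to 6.22). Gpr165, Sema6d and Kcnk12 lost their calls without any library but day 35 WT 3 (−2.01 to −1.07), and Tmem204 without any library but day 35 KO 1 or day 35 WT 3 (−1.34 to −1.18). Nid2 lost its call without day 35 WT 2 (−1.29 to −1.10), and Tmc7 without any library but day 35 KO 2 or day 35 WT 3 (−1.03 to −0.83). Apoe lost its call without day 35 KO 1 or 3 or day 35 WT 1 or 2 (1.94 to 2.48), and Hbb-bt without any library but day 35 KO 1 or day 35 WT 3 (2.14 to 3.13). With a neutrophil marker covariate, added after the data were seen, Ngp turned to log2FC −0.10.

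**Figure D5:**
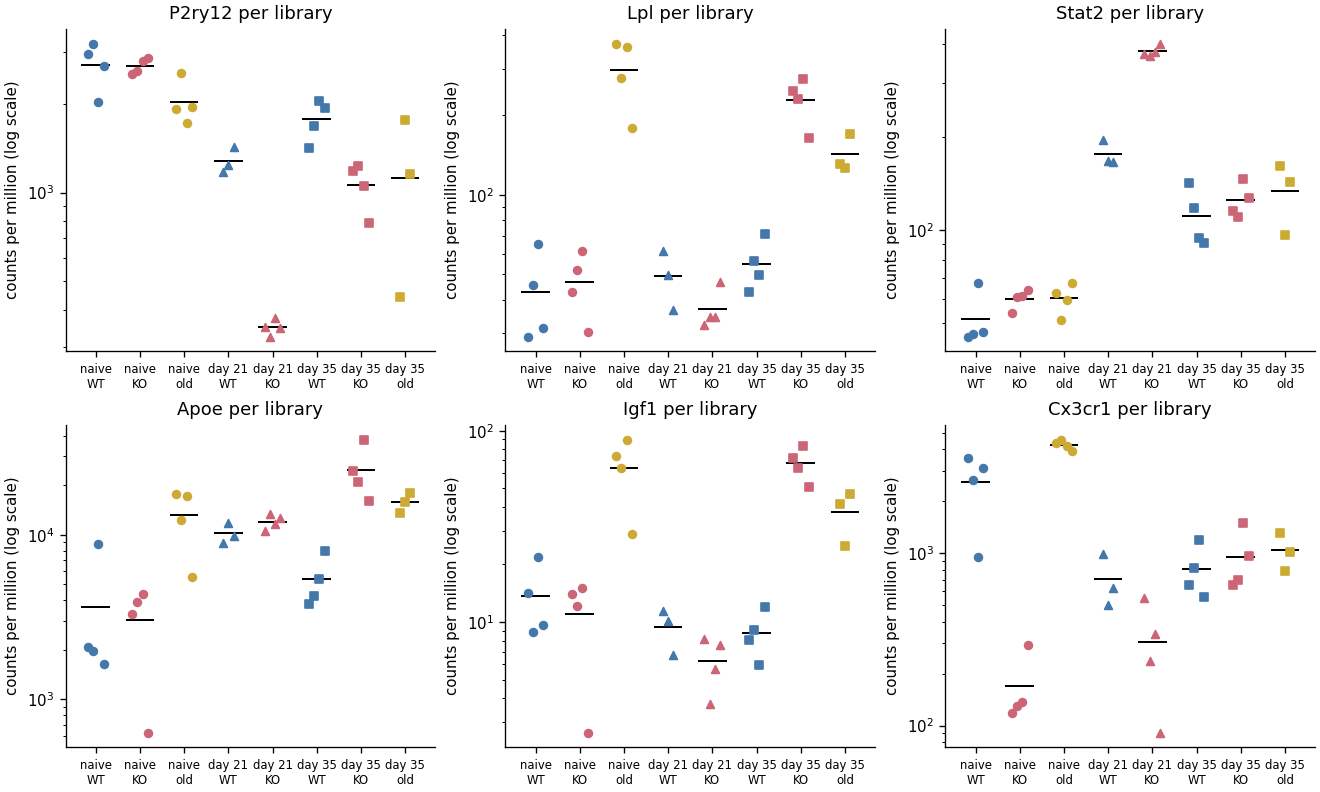
Points are CPM (log scale) of P2ry12, Lpl, Stat2, Apoe, Igf1 and Cx3cr1 in each library of the 8 groups, and lines are group means. P2ry12 is at 349 ± 20.5 in day 21 KO and 1281 ± 133 in day 21 WT, and Lpl at 228 ± 46.8 in day 35 KO and 55.0 ± 12 in day 35 WT (mean ± SD).

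In WT, day 21 (n = 3) was compared with naive (n = 4). Interferon response genes rose at day 21, 27 of 32 (28 over the list alone, camera adjusted p = 4.59e-28, 0.032 estimated). Ifit3 rose from 7.72 ± 2.47 to 44.7 ± 2.47 CPM (log2FC 2.53, SE 0.209, adjusted p = 1.97e-09). Of MHC class I genes 14 of 17 rose (15 over the list alone, camera adjusted p = 1.3e-18, 0.032 estimated). Among them was Tap1 (log2FC 2.01, SE 0.151). Of MHC class II genes 7 of 10 rose (8 over the list alone, camera adjusted p = 3.78e-05, 0.276 estimated). Of cytokines and chemokines 16 of 25 rose (17 over the list alone, camera adjusted p = 4.89e-10, 0.0792 estimated). They included Cxcl10 (log2FC 3.69, SE 0.365). Of disease-associated genes 11 of 27 rose and 1 fell (12 over the list alone, camera adjusted p = 0.000221, 0.521 estimated). The integrin Itgax (log2FC 2.60, SE 0.358) rose and the chemokine Ccl6 (log2FC −1.35, SE 0.196) fell. Homeostatic genes fell, 12 of 24 (12 over the list alone, camera adjusted p = 0.000124, 0.521 estimated). Among them was Fcrls (log2FC −1.33, SE 0.203).

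Neutrophil transcripts were higher in the naive libraries. Of neutrophil markers 12 of 14 fell by day 21 and 1 rose (13 over the list alone, camera adjusted p = 4.89e-10, 0.276 estimated). They included Retnlg (log2FC −8.85, SE 1.54). S100a9 went from 2504 ± 1870 to 5.48 ± 3.73 CPM and the sum from 9102 ± 6100 to 719 ± 13.2. Border macrophage markers fell, 8 of 10 (9 over the list alone, camera adjusted p = 4.75e-06, 0.276 estimated). Monocyte markers fell, 5 of 12 (7 over the list alone, camera adjusted p = 0.00115, 0.521 estimated). Among them was Hp (log2FC −6.43, SE 1.57). Camera also called astrocyte (3 of 12 members, adjusted p = 0.002) and oligodendrocyte (2 of 10, 0.045) genes higher (0.5 to 0.521 estimated). It lost oligodendrocyte without day 21 WT 2 or naive WT 1 or 4 (up to 0.198). The genes that fell furthest are known from granulocytes: Cd177 (log2FC −9.74, SE 2.14, adjusted p = 0.00263) and Camp (−9.27, SE 2.1), Padi4 (1230-fold, 95% interval 219.9 to 48500), Trem3 (at least 119.5-fold), Ear2 (at least 102.8-fold) and Epx (971-fold, 95% interval 173.9 to 38400). Those that rose furthest were the opioid precursor Pdyn (64.4-fold, 95% interval 21.7 to 314.9), the interferon-induced GTPases Gbp2b (log2FC 4.63, SE 0.792), Iigp1 (4.61, SE 0.417) and Gbp8 (4.52, SE 0.502), the chemokine Cxcl9 (log2FC 4.56, SE 0.666) and complement C4b (log2FC 4.53, SE 0.721). edgeR called 2989 genes (1320 higher, 1669 lower). The count was 1727 without day 21 WT 2 and 1933 without day 21 WT 1. With a neutrophil marker covariate, added after the data were seen, Hp turned to log2FC 1.70.

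In WT at day 35 against naive (n = 4 each), 18 of 32 interferon response genes were higher (21 over the list alone, camera adjusted p = 1.71e-12, 0.216 estimated). They included Mx1 (log2FC 1.68, SE 0.21). Of MHC class I genes 12 of 17 rose (12 over the list alone, camera adjusted p = 5.16e-13, 0.216 estimated). Cell cycle genes were lower, 19 of 32 (26 over the list alone, camera adjusted p = 2.24e-08, 0.469 estimated). Among them were the spindle protein Nusap1 (log2FC −3.99, SE 0.894) and the ubiquitin carrier Ube2c (log2FC −4.38, SE 1). Of homeostatic genes 4 of 24 fell (8 over the list alone, camera adjusted p = 0.00477, 0.625 estimated). They included Cx3cr1 (log2FC −1.68, SE 0.447). Neutrophil markers fell in these libraries too, 12 of 14, while 1 rose (12 over the list alone, camera adjusted p = 6.46e-12, 0.216 estimated). Retnlg had log2FC −9.03, SE 1.4, and the sum was 686 ± 92.5 CPM. Camera also called astrocyte (1 of 12 members, adjusted p = 0.0179) and immediate-early (2 of 21, 0.00146) genes higher and monocyte (5 of 12, 8.96e-05) and border macrophage (8 of 10, 1.11e-07) genes lower (0.216 to 0.611 estimated). It lost astrocyte without day 35 WT 3 or 4 or naive WT 1 (up to 0.0968) and immediate-early without naive WT 2 (up to 0.0754). Tissue dissociation can induce immediate-early genes. Genes of granulocyte granules fell furthest: Epx (at least 356.6-fold), Prg2 (1360-fold, 95% interval 376.1 to 11200), Elane (at least 151.4-fold) and Ear6 (at least 136.9-fold), together with the receptor Trem3 (at least 131.6-fold) and the kinase Mapk13 (at least 109-fold). The interferon-induced GTPases Iigp1 (log2FC 3.59, SE 0.41), Gbp8 (3.59, SE 0.497) and Tgtp2 (3.40, SE 0.435), the class I genes H2-Q6 (log2FC 3.46, SE 0.406) and H2-Q7 (3.33, SE 0.395) and the chemokine Cxcl9 (log2FC 3.32, SE 0.658) rose furthest. edgeR called 2645 genes (1166 higher, 1479 lower). The count was 1406 without day 35 WT 1, 1617 without naive WT 2 and 1667 without day 35 WT 2. With a neutrophil marker covariate, added after the data were seen, the log2FC of Nusap1 and Ube2c turned to 0.03 and 0.40.

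Between day 21 (n = 3) and day 35 (n = 4) of WT, interferon response genes fell, 4 of 32 (27 over the list alone, camera adjusted p = 2.12e-40, 0.00771 estimated). They were Ifit3 (log2FC −1.09, SE 0.195, adjusted p = 0.0287) and Oas1a (−1.10, SE 0.216), Oasl1 (−1.51, SE 0.296) and Ifit1 (−1.49, SE 0.297). Of MHC class I genes 1 of 17 fell (9 over the list alone, camera adjusted p = 6.88e-13, 0.0892 estimated), Tap1 (log2FC −0.81, SE 0.147), and Gimap6 (log2FC 1.08, SE 0.218) rose. Camera also called immediate-early (0 of 21 members, adjusted p = 0.000287) genes higher and erythroid (0 of 5, 0.043) genes lower (0.657 to 0.66 estimated). It lost immediate-early without day 35 WT 1 (up to 0.104) and erythroid without day 21 WT 3 or day 35 WT 1 or 2 (up to 0.443). edgeR called 9 genes (1 higher, 8 lower; 935 at an unadjusted p under 0.05). DESeq2 called 74. The count was 0 without day 21 WT 1 or 3 or day 35 WT 2 or 4 (656 to 893 at an unadjusted p under 0.05), 1 without day 21 WT 2 and 2 without day 35 WT 3, and 4 with day 35 WT 3 moved to KO. Ifit3 lost its call without any library but day 35 WT 1 or 3 (log2FC −1.22 to −0.93). Oas1a, Oasl1 and Tap1 lost their calls without any library but day 35 WT 1 (−1.63 to −0.77), and Ifit1 without any library but day 35 WT 3 (−1.79 to −1.36). Gimap6 lost its call without any of the 7 libraries (1.01 to 1.18).

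In KO, day 21 was compared with naive (n = 4 each). Interferon response genes rose, 31 of 32 (31 over the list alone, camera adjusted p = 2.82e-25, 0.0358 estimated). Among them was Stat2 (log2FC 2.66, SE 0.153), and interferon beta, Ifnb1, rose 98.5-fold, 95% interval 33.3 to 480.9. Of cytokines and chemokines 20 of 25 rose and 1 fell (22 over the list alone, camera adjusted p = 3.94e-09, 0.0908 estimated). Homeostatic genes fell, 20 of 24 (20 over the list alone, camera adjusted p = 2.26e-11, 0.415 estimated). P2ry12 went from 2693 ± 165 to 349 ± 20.5 CPM (log2FC −2.95, SE 0.253, adjusted p = 8.69e-10). Of monocyte markers 3 of 12 rose (3 over the list alone, camera adjusted p = 0.0488, 0.783 estimated). They included Fn1 (log2FC 3.69, SE 0.796). Of neutrophil markers 12 of 14 fell (12 over the list alone, camera adjusted p = 0.00823, 0.712 estimated). Of B and plasma cell markers 5 of 5 fell (5 over the list alone, camera adjusted p = 0.00362, 0.0358 estimated). Camera also called T and NK cell (6 of 10 members, adjusted p = 0.00362) and astrocyte (1 of 12, 0.0325) genes higher (0.415 to 0.712 estimated). It lost astrocyte without naive KO 1 or 3 (up to 0.0854). Furthest up were Nos2 (639-fold, 95% interval 176.5 to 5280), Arg1 (log2FC 6.73, SE 1.46) and complement factor Cfb (log2FC 6.45, SE 0.623). Furthest down were the eosinophil granule gene Prg2 (326.4-fold, 95% interval 58.2 to 12900), the immunoglobulin Igha (log2FC −5.42, SE 1.21), the potassium channel Kcnj12 (log2FC −5.27, SE 0.822) and D7Ertd443e (46.1-fold, 95% interval 15.5 to 225.7). edgeR called 6272 genes (3123 higher, 3149 lower). Atg7 did not pass (log2FC 0.70, SE 0.3, adjusted p = 0.0601) but did without naive KO 3 (log2FC 1.00, adjusted p = 0.011), and the monocyte call ended without day 21 KO 1, 2 or 4 or naive KO 4 (camera adjusted p up to 0.182).

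In KO at day 35 against naive (n = 4 each), disease-associated genes rose, 15 of 27 (17 over the list alone, camera adjusted p = 4.26e-11, 0.182 estimated). Apoe went from 3042 ± 1670 to 24820 ± 9360 CPM (log2FC 3.03, SE 0.542, adjusted p = 0.000539), and Lpl (log2FC 2.29, SE 0.269) and Csf1 (2.41, SE 0.236) rose. Interferon response genes rose, 24 of 32 (26 over the list alone, camera adjusted p = 3.21e-19, 0.102 estimated). Of cytokine and chemokine genes 14 of 25 rose (15 over the list alone, camera adjusted p = 1.42e-10, 0.102 estimated). Homeostatic genes fell, 14 of 24 (17 over the list alone, camera adjusted p = 5.83e-07, 0.436 estimated). Among them was P2ry12 (log2FC −1.34, SE 0.239), while 1 of them, Cx3cr1, the Cre locus, rose from its low naive level (log2FC 2.50, SE 0.462, adjusted p = 0.000715). Whether Cre allele number differed was not tested. Astrocyte markers rose, 12 of 12 (12 over the list alone, camera adjusted p = 2.78e-09, 0.116 estimated). They included the water channel Aqp4 (log2FC 2.46, SE 0.56). Camera also called oligodendrocyte (6 of 10 members, adjusted p = 0.00109), neuron (9 of 11, 0.00163), erythroid (5 of 5, 0.000514) and immediate-early (14 of 21, 1.96e-07) genes higher and border macrophage (6 of 10, 1 opposite, 0.00322) genes lower (0.3 to 0.444 estimated). Furthest up were the apolipoproteins Apoc1 (log2FC 5.27, SE 0.635) and Apoc4 (158.2-fold, 95% interval 27.9 to 6290), Ifnb1 (133.7-fold, 95% interval 45.4 to 651.1) and the actin-related Actr3b (log2FC 4.32, SE 0.577). Furthest down were the border macrophage receptors Lyve1 (log2FC −4.51, SE 0.838) and Cd163 (−2.92, SE 0.636), Prg2 (log2FC −5.49, SE 1.43) and Kl (log2FC −2.84, SE 0.74). edgeR called 2970 genes (1608 higher, 1362 lower). The count was 1597 without day 35 KO 4 and 1979 without naive KO 2, and Atg7 (log2FC 0.68, SE 0.299, adjusted p = 0.103) passed without naive KO 3 (log2FC 0.98, adjusted p = 0.0295).

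Between day 21 and day 35 of KO (n = 4 each), homeostatic genes rose, 18 of 24 (20 over the list alone, camera adjusted p = 5.61e-10, 0.409 estimated). Among them was Gpr34 (log2FC 2.29, SE 0.233). Of disease-associated genes 10 of 27 rose (11 over the list alone, camera adjusted p = 0.000192, 0.457 estimated). They included Lpl (log2FC 2.62, SE 0.275) and Igf1 (3.41, SE 0.42). Interferon response genes fell, 29 of 32 (30 over the list alone, camera adjusted p = 3.75e-21, 0.0482 estimated). Among them was Stat2 (log2FC −1.60, SE 0.146). T and NK cell markers fell, 10 of 10 (10 over the list alone, camera adjusted p = 8.93e-08, 0.0482 estimated). B and plasma cell markers rose, 4 of 5 (5 over the list alone, camera adjusted p = 0.0013, 0.0482 estimated). Neutrophil markers rose, 7 of 14 (10 over the list alone, camera adjusted p = 0.00999, 0.496 estimated). They included S100a8 (log2FC 4.37, SE 1.3). Camera also called astrocyte (6 of 12 members, adjusted p = 0.00605), oligodendrocyte (3 of 10, 0.0155), neuron (9 of 11, 0.00605), erythroid (5 of 5, 2.55e-06) and immediate-early (7 of 21, 0.000382) genes higher and monocyte (3 of 12, 0.0013) and border macrophage (5 of 10, 0.00076) genes lower (0.119 to 0.466 estimated). It lost oligodendrocyte without day 35 KO 4 (up to 0.0984) and neuron without day 35 KO 4 (up to 0.0795). Summed monocyte markers went from 2734 ± 343 to 1220 ± 224 CPM. The furthest risen genes were the immunoglobulin joining chain Jchain (62.8-fold, 95% interval 21.2 to 307), the globins Hbb-bt (184.8-fold, 95% interval 50.8 to 1530) and Hba-a2 (log2FC 5.34, SE 0.863) and Igha (log2FC 5.81, SE 1.21). The furthest fallen were Nos2 (log2FC −6.87, SE 1.03), the NK receptor Klrk1 (log2FC −5.09, SE 1.06), Cfb (log2FC −4.66, SE 0.538) and Arg1 (−4.60, SE 1.25). edgeR called 3462 genes (1843 higher, 1619 lower). The neutrophil call ended without day 35 KO 4 (camera adjusted p = 0.0632). The call of S100a8 ended without day 35 KO 4 as well (log2FC 2.76 to 4.74 over the single-library fits).

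The genotype by day interactions test whether the change from naive differed between KO and WT. At day 21, 13 of 24 homeostatic genes had the lower change in KO, and 1 the higher (21 over the list alone, camera adjusted p = 7.14e-10, 0.343 estimated). Among them was Gpr34 (log2FC −2.27, SE 0.327). The change was higher in KO for 16 of 32 cell cycle genes (28 over the list alone, camera adjusted p = 3.45e-12, 0.343 estimated). It was higher too for 6 of 32 interferon response genes (14 over the list alone, camera adjusted p = 4.31e-07, 0.343 estimated). They included Stat2 (log2FC 0.88, SE 0.215). It was also higher for 8 of 12 monocyte markers (12 over the list alone, camera adjusted p = 5.39e-08, 0.343 estimated). Among them was Ly6c2 (log2FC 6.81, SE 1.83). Camera also called border macrophage (5 of 10 members, adjusted p = 5.69e-07), T and NK cell (2 of 10, 3e-04) and neutrophil (1 of 14, 1 opposite, 0.00131) genes higher and B and plasma cell (3 of 5, 0.00175) and erythroid (0 of 5, 0.0154) genes lower (0.0597 to 0.704 estimated). It lost erythroid without day 21 WT 3 or naive WT 1 (up to 0.0887). The largest interactions were those of the nucleoside transporter Slc28a2 (log2FC 8.02, SE 1.85), Ms4a8a (log2FC 8.0, SE 2.01) and Slfn4 (7.43, SE 2.09) and the lectin Chil3 (log2FC 7.23, SE 2.15) upward, and of the chemokine Cxcl13 (log2FC −4.40, SE 1.06), Kcnj12 (log2FC −6.00, SE 1.17), the collagen cross-linker Lox (log2FC −4.67, SE 0.667) and Adcy8 (log2FC −3.77, SE 0.568) downward. edgeR called 1343 genes (655 higher, 688 lower). The count was 514 without day 21 WT 3, 563 without day 21 WT 2, 588 without naive WT 3 and 862 without day 21 KO 2, and Atg7 (log2FC 1.14, SE 0.443, adjusted p = 0.0975) passed without naive KO 3 (log2FC 1.45, adjusted p = 0.0384). Ms4a8a and Ly6c2 lost their calls without day 21 WT 2 or 3 or naive WT 3 (log2FC 6.09 to 11.72). Slfn4 lost its call without day 21 WT 1, 2 or 3 or naive WT 3 (6.73 to 8.08), and Chil3 without any library but day 21 KO 3, day 21 WT 1 or naive WT 1 or 2 (6.28 to 9.62).

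For day 35, 3 of 27 disease-associated genes had the higher change from naive in KO (12 over the list alone, camera adjusted p = 5.64e-08, 0.476 estimated). Called members included Igf1 (log2FC 3.26, SE 0.563) and Lpl (1.93, SE 0.374), and Cx3cr1, which was low in naive KO, had log2FC 4.18, SE 0.642, adjusted p = 0.00597. Neutrophil markers had the higher change in KO, 2 of 14 (12 over the list alone, camera adjusted p = 4.26e-10, 0.376 estimated). They were S100a8 (log2FC 8.99, SE 1.9) and S100a9 (8.21, SE 1.81). The sum of the 14 markers went from 9102 ± 6100 to 686 ± 92.5 CPM in WT and from 2389 ± 1170 to 1740 ± 1440 in KO. Camera also put monocyte, border macrophage, astrocyte, oligodendrocyte, neuron, erythroid and immediate-early genes higher, with no member called by edgeR (adjusted p = 0.00024, 0.011, 0.000154, 0.0275, 0.00427, 6.78e-05 and 0.0275; 0.487, 0.487, 0.476, 0.487, 0.487, 0.376 and 0.632 estimated). Of these it lost border macrophage without day 35 WT 3 or naive KO 4 (up to 0.166), oligodendrocyte without day 35 KO 1 or 4, day 35 WT 1 or 2, naive KO 1 or 3 or naive WT 2 (up to 0.164), neuron without day 35 KO 4 (up to 0.0819) and immediate-early without day 35 WT 3 or 4, naive KO 1, 2 or 3 or naive WT 1 or 4 (up to 0.466). Further genes were Apoc4 (log2FC 7.60, SE 1.73) and Ifnb1 (4.72, SE 1.08) upward and Ajm1 (log2FC −1.16, SE 0.25), Ak1 (−1.0, SE 0.209), Pqlc2 (−0.98, SE 0.198) and Spns2 (−0.98, SE 0.204) downward. edgeR called 51 genes (33 higher, 18 lower; 2473 at an unadjusted p under 0.05). The count was 7 without naive KO 2 or naive WT 3, 9 without day 35 WT 1, 10 without day 35 WT 2, 18 without day 35 KO 4, 27 without naive KO 1, 33 without day 35 KO 1 or 3 or naive WT 2 and 190 without naive WT 1, and 13 with day 35 WT 3 moved to KO. S100a8 lost its call without any library but day 35 KO 1, 2 or 3 or naive WT 1 or 4 (log2FC 7.38 to 9.73). S100a9 lost its call without any library but day 35 KO 3 or naive WT 1 (6.74 to 8.68), and Apoc4 without any library but day 35 KO 2, day 35 WT 4 or naive WT 1 or 4 (5.26 to 9.14). Ifnb1 lost its call without any library but day 35 WT 3 or naive WT 1 or 2 (3.24 to 5.64), and Ajm1 without any library but day 35 KO 1 or 2, day 35 WT 3, naive KO 1 or 4 or naive WT 1 (−1.24 to −1.06). Ak1 lost its call without day 35 KO 2 or 4, day 35 WT 2, naive KO 1 or 2 or naive WT 3 (−1.07 to −0.92), and Pqlc2 without day 35 KO 4, day 35 WT 1 or 2, naive KO 2 or naive WT 3 (−1.09 to −0.84). Spns2 lost its call without day 35 KO 3 or 4, day 35 WT 1, naive KO 2 or 3 or naive WT 2 or 3 (−1.09 to −0.89), and Igf1 without naive WT 3 (2.93 to 3.44). Lpl lost its call without day 35 WT 1 or 2, naive KO 2 or naive WT 3 (1.64 to 2.09).

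From day 21 to day 35, the change was higher in KO than in WT for 6 of 27 disease-associated genes (16 over the list alone, camera adjusted p = 1.15e-09, 0.296 estimated). Examples were Lpl (log2FC 2.46, SE 0.388) and Igf1 (3.49, SE 0.607). Erythroid markers had the higher change, 5 of 5 (5 over the list alone, camera adjusted p = 9.56e-09, 0.0424 estimated), and B and plasma cell markers, 1 of 5 (4 over the list alone, camera adjusted p = 0.00198, 0.0424 estimated). T and NK cell markers had the lower, 1 of 10 (5 over the list alone, camera adjusted p = 1.12e-07, 0.0424 estimated). Camera also called neutrophil (0 of 14 members, adjusted p = 0.0132), oligodendrocyte (1 of 10, 0.00107), astrocyte (0 of 12, 0.000305) and neuron (1 of 11, 0.000477) genes higher and monocyte (0 of 12, 0.00258) and border macrophage (0 of 10, 0.000583) genes lower (0.436 to 0.625 estimated). It lost neutrophil without day 35 KO 4 or day 35 WT 3 (up to 0.0916). The largest were the globins Hbb-bt (log2FC 8.40, SE 1.3), Hba-a2 (6.45, SE 1.12) and Hbb-bs (6.28, SE 1.18) and the synaptic scaffold Shank3 (log2FC 5.64, SE 1.53) upward, and Nos2 (log2FC −6.14, SE 1.49), the interleukin 2 receptor subunit Il2rb (log2FC −5.90, SE 1.3), Tgfbi (log2FC −2.98, SE 0.736) and Ly6a (−1.91, SE 0.379) downward. edgeR called 370 genes, of which 258 were higher. The count was 123 without day 21 WT 2, 143 without day 21 WT 3, 176 without day 35 WT 1, 2.1e+02 (54 lower) without day 21 KO 2, 209 without day 35 WT 2, 216 without day 35 KO 1 and 224 without day 35 KO 2, and 769 with day 35 WT 3 moved to KO. Groups with at most 3 counts enter the values of Hbb-bt here and of Ms4a8a, Apoc4 and Ifnb1 in the interactions with naive, so these are no bounds. Shank3 lost its call without any library but day 21 KO 4, day 35 KO 3 or day 35 WT 3 (log2FC 5.04 to 6.85). Nos2 lost its call without day 21 WT 2 or 3, day 35 KO 1 or 2 or day 35 WT 1 or 2 (−7.08 to −5.42), and Il2rb without day 21 WT 3 or day 35 WT 1 (−9.34 to −5.17). Tgfbi lost its call without day 21 KO 2, day 21 WT 2 or 3, day 35 KO 1 or 2 or day 35 WT 1 or 2 (−3.55 to −2.75).

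Age without EAE was tested as naive old against naive young WT (n = 4 each). Here and below, old mice may also differ in Cre status and tamoxifen. Disease-associated genes rose with age, 22 of 27 (26 over the list alone, camera adjusted p = 2.41e-28, 0.0324 estimated). Lpl went from 42.9 ± 16.6 to 297 ± 89.6 CPM (log2FC 2.80, SE 0.276, adjusted p = 1.74e-06), and the integrin Itgax (log2FC 2.88, SE 0.347) and the protease inhibitor Cst7 (log2FC 3.46, SE 0.512) rose. Lysosome genes rose, 14 of 44 (27 over the list alone, camera adjusted p = 2.9e-10, 0.19 estimated). Of cholesterol export genes 7 of 16 rose (7 over the list alone, camera adjusted p = 3.66e-07, 0.0626 estimated). MHC class I genes rose, 11 of 17 (14 over the list alone, camera adjusted p = 7.62e-14, 0.0626 estimated). They included H2-D1 (log2FC 1.28, SE 0.199). Of interferon response genes 10 of 32 rose (17 over the list alone, camera adjusted p = 2.73e-12, 0.108 estimated). Of cytokines and chemokines 9 of 25 rose and 1 fell (12 over the list alone, camera adjusted p = 4.64e-09, 0.0626 estimated).

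The genes that rose furthest with age were the proton pump subunit Atp6v0d2 (log2FC 4.87, SE 0.796), the immunoglobulin Ighg3 (log2FC 6.35, SE 1.18), Pianp (log2FC 5.80, SE 0.891), the elastase Mmp12 (log2FC 4.97, SE 0.569), the Wnt inhibitor Dkk2 (log2FC 4.38, SE 0.832) and the lysozyme Lyz1 (log2FC 4.31, SE 0.804). Those that fell furthest were Rgs7bp (log2FC −2.47, SE 0.409), the estrogen receptor Esr1 (log2FC −2.35, SE 0.416), Gpr165 (log2FC −2.27, SE 0.454), the endothelin receptor Ednrb (log2FC −2.03, SE 0.443) and Sema6d (log2FC −1.49, SE 0.344). Summed neutrophil markers were 9277 ± 3040 CPM in old and 9102 ± 6100 in young mice (exact permutation p = 1, adjusted p = 1). Camera also called T and NK cell (0 of 10 members, adjusted p = 0.0466) genes higher and astrocyte (1 of 12, 1 opposite, 0.00801) genes lower (0.444 estimated). It lost T and NK cell without naive WT 1 or 2 or naive old 3 (up to 0.132). edgeR called 1135 genes (698 higher, 437 lower). The count was 494 without naive WT 4, 567 without naive old 3, 598 without naive WT 1 and 617 without naive old 1.

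At day 35, old mice (n = 3) were compared with young WT (n = 4), and its edgeR calls rest on day 35 old 1. Neutrophil markers were higher in old mice, 12 of 14 (13 over the list alone, camera adjusted p = 2.56e-11, 0.229 estimated). Their sum was 32470 CPM in day 35 old 1, 2482 in day 35 old 2 and 697.1 in day 35 old 3, against 686 ± 92.5 in young WT. Monocyte markers were higher, 10 of 12 (12 over the list alone, camera adjusted p = 2.04e-05, 0.355 estimated). Among them was Hp (log2FC 6.57, SE 1.4). Likewise called were 27 of 32 cell cycle genes (28 over the list alone, camera adjusted p = 2.34e-14, 0.299 estimated). They included Ube2c (log2FC 4.87, SE 1.02). Disease-associated genes were higher, 11 of 27 (13 over the list alone, camera adjusted p = 5.13e-08, 0.299 estimated). Examples were Igf1 (log2FC 2.10, SE 0.419) and Lpl (1.37, SE 0.278). Furthest up were the granule genes Ltf (log2FC 9.25, SE 1.64, adjusted p = 0.0101) and S100a8 (9.33, SE 1.66) and Camp (9.56, SE 1.87), Cd177 (log2FC 9.40, SE 1.77), Serpinb1a (603-fold, 95% interval 205.9 to 2930) and Mapk13 (at least 117.6-fold). Furthest down were Sema6d (log2FC −1.40, SE 0.406), the metalloprotease Mmp28 (log2FC −1.36, SE 0.429), the myosin Myo18b (log2FC −1.21, SE 0.285), the channel Kcnk12 (log2FC −1.21, SE 0.314), the RNA-binding Elavl4 (log2FC −1.17, SE 0.328) and Zfp827 (log2FC −1.12, SE 0.27). edgeR called 1312 genes (1043 higher, 269 lower; 3245 at an unadjusted p under 0.05). The count was 0 without day 35 old 1, 600 without day 35 WT 2, 663 without day 35 WT 1, 793 without day 35 WT 4 and 2044 without day 35 old 3. Without day 35 old 1, edgeR had 1377 genes at an unadjusted p under 0.05 and DESeq2 called 50. With the neutrophil covariate edgeR called 0, with 838 at an unadjusted p under 0.05, and Hp turned to log2FC −1.64. The monocyte call ended without day 35 old 1 (camera adjusted p = 0.0505), and Atg7 (log2FC 0.81, SE 0.319, adjusted p = 0.112) passed without day 35 old 3 (log2FC 1.07, adjusted p = 0.0308). Each gene named for day 35 age lost its call in some fit: Ltf, S100a8, Camp, Cd177, Ube2c and Hp without day 35 old 1 (log2FC 2.15 to 10.14). Mapk13 and Serpinb1a lost their calls without day 35 old 1, and Sema6d without any library but day 35 WT 3 or 4 or day 35 old 2 (−2.0 to −1.16). Mmp28 lost its call without any library but day 35 WT 3 or day 35 old 2 (−2.11 to −0.90), and Myo18b, Kcnk12 and Zfp827 without day 35 old 1 (−1.86 to −0.77). Elavl4 lost its call without day 35 WT 2 or day 35 old 1 (−1.35 to −0.76), and Igf1 and Lpl without day 35 old 1 (1.22 to 2.32).

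In old mice, day 35 (n = 3) was compared with naive (n = 4). Interferon response genes rose, 16 of 32 (21 over the list alone, camera adjusted p = 2.1e-08, 0.322 estimated). They included Stat2 (log2FC 1.15, SE 0.157) and interferon beta, Ifnb1 (log2FC 5.37, SE 0.762). Of MHC class I genes 10 of 17 rose (11 over the list alone, camera adjusted p = 0.000657, 0.47 estimated). Homeostatic genes fell, 10 of 24 (11 over the list alone, camera adjusted p = 2.74e-07, 0.47 estimated). Among them was Cx3cr1 (log2FC −2.04, SE 0.502). Astrocyte markers were higher at day 35, 11 of 12 (12 over the list alone, camera adjusted p = 1.91e-07, 0.322 estimated). They included Aqp4 (log2FC 2.96, SE 0.706). Camera also called immediate-early (6 of 21 members, adjusted p = 0.00081) and oligodendrocyte (2 of 10, 0.0163) genes higher and border macrophage (7 of 10, 1.73e-05) genes lower (0.322 to 0.487 estimated). It lost oligodendrocyte without day 35 old 2 or 3 (up to 0.171). For monocyte and neutrophil genes camera gave lower (adjusted p = 0.0463 and 0.00885) but medians of log2FC higher (0.084 and 0.228), and no member was called. Furthest up were also Fam71a (log2FC 4.34, SE 1.09) and the synaptic Rph3a (log2FC 3.75, SE 0.956). Furthest down were the border macrophage genes Cbr2 (log2FC −3.53, SE 0.725) and Cd163 (−3.57, SE 0.706), the lectin Cd209a (log2FC −4.33, SE 0.845) and the eosinophil peroxidase Epx (log2FC −3.75, SE 0.924). edgeR called 2555 genes (1440 higher, 1115 lower). The count was 973 without day 35 old 3 and 1673 without naive old 1, and camera lost the homeostatic list without day 35 old 1 (adjusted p = 0.0605).

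The age by day 35 interaction tests whether the change from naive to day 35 differed between old and young WT mice. The collagen cross-linker Lox (log2FC −3.64, SE 0.601, adjusted p = 0.0106), the collagen Col6a3 (log2FC −1.58, SE 0.225, adjusted p = 0.00136) and the peptidase Naalad2 (log2FC −1.59, SE 0.286, adjusted p = 0.0193) had the lower change in old mice, and the circadian repressor Cry2 (log2FC 1.15, SE 0.197, adjusted p = 0.0122) the higher. No member of a list was called over all genes. Camera put disease-associated genes lower (4 over the list alone, camera adjusted p = 3.21e-12, 0.344 estimated) and neutrophil markers higher (12 over the list alone, camera adjusted p = 1.6e-09, 0.43 estimated). Camera also called monocyte (0 of 12 members, adjusted p = 0.0312), astrocyte (0 of 12, 0.000115) and erythroid (0 of 5, 0.0166) genes higher (0.463 to 0.739 estimated). It lost monocyte without day 35 WT 3, day 35 old 1, naive WT 3 or naive old 1 or 2 (up to 0.617) and erythroid without day 35 WT 1, day 35 old 2 or 3, naive WT 2 or naive old 2 (up to 0.0977). edgeR called 6 genes (3 higher, 3 lower; 1630 at an unadjusted p under 0.05). The count was 3 without naive old 1 or 2, 10 without naive WT 1, 21 without naive WT 3, 135 without day 35 old 2 and 347 without day 35 old 3. The call ended for Naalad2 without day 35 WT 2 or 3, naive WT 4 or naive old 1 or 2 (log2FC −1.75 to −1.47).

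KO and age effects share the young WT libraries. At day 35, 147 genes were higher and 64 lower in both (18.6 and 2.23 expected if independent). Neither can be told apart from EAE severity, higher in both groups. The covariance of the log2FC was 0.579 (r = 0.796 across genes, which are not independent replicates), against a mean of 0.081 (r = 0.47) in 20 simulations of unchanged groups sharing a control, which had 0 genes in common. When the WT libraries were divided between the KO and age contrasts in 6 ways, 0 to 3 genes were shared with covariances of 0.435 to 0.655, and without day 35 old 1 the number was 0. In naive mice 26 genes were shared (24 higher, 2 lower; 1.66 and 0.22 expected), with a covariance of 0.112 (r = 0.334) against 0.084 (r = 0.516) and 0 genes in the simulations, and 0 to 8 genes with covariances of −0.061 to 0.111 in the divided controls. The naive count was 50 without naive KO 4, 40 without naive WT 3, 14 without naive KO 1 or naive WT 1, 11 without naive WT 2, 8 without naive KO 2, and 7 without naive KO 3 or naive WT 4. The day 35 count was 31 without day 35 WT 2, 45 without day 35 KO 3, 48 without day 35 WT 1, 75 without day 35 WT 4, 98 without day 35 KO 2, 99 without day 35 KO 1 and 115 without day 35 KO 4. The day 35 KO effect and the naive age effect share no library. They had 199 genes in common in the same direction (160 higher, 39 lower; 12.5 and 3.62 expected) and 2 in opposite directions, with a covariance of 0.093 (r = 0.204). The count was 39 without day 35 WT 2, 45 without day 35 KO 3, 56 without day 35 WT 1, 85 without day 35 WT 4, 85 higher and 16 lower without day 35 KO 1, 107 without day 35 KO 2, 95 higher and 21 lower without naive WT 4, 99 higher and 21 lower without naive old 1, 108 higher and 22 lower without day 35 KO 4 and 131 without naive old 3, and 355 without day 35 old 1 (14296 genes tested). The covariance was 0.054 without naive WT 1 and 0.166 without naive WT 3. Lpl (log2FC 2.05 in day 35 KO, 2.80 in naive old mice) and Sema6d (−1.47 and −1.49) are examples.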

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

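Chosen only after the results had been seen were the tests with the sex covariate, of day 35 old 1 and its neutrophil markers, and of other divisions of the libraries.

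Neutrophil markers were higher in naive than in EAE libraries of WT, with S100a9 at 2504 ± 1870 CPM and Ngp at 1785 ± 1230 in naive WT and 6.67 ± 4.79 and 6.02 ± 5.88 at day 35. As stated, the sort label does not show a Ly6G gate for every library. Thinning every library to the lowest total (log2 ratio of sums −3.66, −3.67 before) cannot test depth, as it keeps expected CPM. RNA of neutrophils may have entered the naive libraries: within their groups the 14 markers varied together over the 12 naive libraries (mean correlation 0.819, against at most 0.331 in 1000 random lists), although Csf3r rose in WT EAE and is also made by microglia. Whether EAE itself altered these transcripts within microglia stays open and was not tested.

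At day 21, monocyte markers were higher and homeostatic genes lower in KO. Monocytes diluting unaltered microglia would lower homeostatic genes by 1 factor only if monocytes lack them, which was not tested. The 14 picked when the test was written had unequal log2FC (−2.39 for Gpr34 to −0.25 for Crybb1). Cochran's Q was 83.2 over genes of the same libraries (chi-square p = 2.73e-12). This cannot exclude dilution. Uneven sex of the pools cannot be told apart from genotype. Xist was 70 to 772.2 CPM in day 21 KO and 1455 to 2042 in WT. With the sex covariate 12 of 24 homeostatic genes were still called lower (19 without). The median log2FC was −0.88 (median SE 0.243) with it and −0.90 (0.207) without. Of 12 monocyte markers 3 were still called higher (6 without), at a median log2FC of 3.35 (SE 1.47), against 3.56 (1.32). An effect of genotype may be part of the pattern and stays open, as does entry of monocytes, though a CD45int gate, where it was used, leaves out cells with high CD45, as infiltrating monocytes have.

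Between old and young WT mice at day 35, the calls rest on day 35 old 1: without it edgeR called 0 genes, with 1377 at an unadjusted p under 0.05, and DESeq2 called 50. Of 14 neutrophil markers 13 were highest in that library among all of day 35, so RNA of other cells in this library is a candidate source. Without it camera still called 16 of 30 lists. Over the fits without 1 library, disease-associated genes stayed higher in old mice (camera adjusted p at most 3.39e-05, but 0.299 estimated with all libraries). Igf1 and Lpl had log2FC of at least 1.91 and 1.22. An effect of age stays open, as does EAE severity.

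Divisions of the same libraries into other groups of the same sizes tested whether chance could give as many genes. The real count was the highest of 35 divisions for day 21 KO (2642, highest other 608) and day 35 KO (363, 51) against WT. So it was for WT day 21 (2989, 1702) and day 35 (2645, 40) against naive and day 35 against 21 (9, 1). KO did likewise, in order (6272, 6), (2970, 494) and (3462, 10). So did naive old against young (1135, 322) and old day 35 against naive (2555, 1692). Unadjusted, this argues against chance only weakly. The 608, 1702, 1692 and 1 come from nearly the real groups reversed, so they do not measure chance. Chance cannot be excluded for naive KO (40, 117) or day 35 old (1312, 1605) against WT. Exchanging libraries within a day can make a group difference an interaction, so this cannot judge interactions. Genotype by day 21 had (1343, 44), by day 35 (51, 37) and by day 21 to 35 (370, 1917). Age by day 35 had (6, 2136). The naive KO division with 117 exchanged naive WT 3 and naive KO 4, far from their groups.

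Of 117 groups of 4 values, 12 had 1 library far from the other 3, with 5.85 expected by chance at 1 in 20. Naive WT 2 had a total of 4.713 in units of 1e6 counts (others 6.461 to 6.765), 15.5% of counts in Gm42418 (Wilson interval 15.5 to 15.6; others 3.63 to 5.63), and summed astrocyte and neuron markers of 220.5 (180.8 to 187.2) and 40.34 CPM (16.54 to 20.19). Naive WT 3 had Apoe at 8838 CPM (1630 to 2079) and B and plasma cell markers at 282.5 (332.8 to 340.1). Naive KO 4 had Cx3cr1 at 291.5 CPM (117.8 to 136.4) and neutrophil markers at 642.2 (2838 to 3099). Naive old 4 had neutrophil markers at 13830 CPM (7476 to 8019). Day 21 KO 4 had an EAE score of 2.75 (3 in the others) and Atg7 at 36.89 CPM (30.98 to 31.72), and day 21 KO 1 had erythroid markers at 0.7851 CPM (3.896 to 4). Changes differed between groups in the interactions, in the order above (1343, 51, 370 and 6 genes by edgeR).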

How the results depend on the processing

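Chosen only after the results had been seen were the fit without day 35 old 1, naive KO 4 and naive WT 3 (each the farthest of its group, over 40 units on 2 principal components; day 35 old 3, at 42.4, was kept since 1 library would have remained), the neutrophil and sex covariates, and the alternatives for the overlap of day 35 KO with naive age. In WT the neutrophil covariate runs nearly along the contrast of naive with EAE, so it also takes up effects of EAE. Libraries could not be paired, as the labels give no replicate numbers that link them across groups. Libraries with the same i5 index were not more alike (mean r −0.012 over 98 pairs) than those with another (0.004 over 295 pairs). At these depths 28.9 to 72.6% of simulated 2-fold changes were recovered, so absent calls are not absent effects.

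Comparisons are named in short here, by KO or old for the difference from WT of that day, WT, KO or old with a day for the change from naive, and genotype or age for interactions. With RLE scaling and with the stricter filter each of the 16 counts stayed within 1.5 times the reported one, and no alternative moved the median log2FC of all genes by more than −0.048 to 0.04. Counts that moved further follow for each alternative, and the cause was not tested except where fewer genes or libraries are part of the alternative. With an absolute log2FC of at least 1: naive KO 20, day 21 KO 1050, day 35 KO 1.4e+02 (135 higher, 7 lower), WT day 21 1004, WT day 35 877, WT day 35 vs 21 5, KO day 21 2475, KO day 35 1063, KO day 35 vs 21 1412, genotype by day 21 750, genotype by day 35 33, genotype by day 21 to 35 221, naive old 398, day 35 old 778 and old day 35 816. With DESeq2: naive KO 70, day 35 KO 682, WT day 35 vs 21 74, genotype by day 35 483 (377 higher, 106 lower), genotype by day 21 to 35 707 and age by day 35 220 (186 higher, 34 lower). Without a filter: day 35 KO 143, WT day 35 vs 21 14, genotype by day 21 845 and day 35 old 849. With the index block: WT day 35 vs 21 22, day 35 old 647 and age by day 35 10. With day 35 WT 3 moved to KO: day 35 KO 1.7e+02 (80 higher, 90 lower), WT day 35 vs 21 4, genotype by day 35 13 and genotype by day 21 to 35 769. With only the groups compared: naive KO 18, day 21 KO 4408, day 35 KO 559, WT day 35 vs 21 93, genotype by day 21 2516, genotype by day 35 119, genotype by day 21 to 35 1104, naive old 675, day 35 old 0 and old day 35 180. Without the 3 libraries: naive KO 192, day 35 KO 1280, WT day 35 vs 21 117, genotype by day 35 251, genotype by day 21 to 35 1192, naive old 1925, day 35 old 19 and age by day 35 80. With the neutrophil covariate: day 35 KO 167, WT day 21 1697, WT day 35 703, WT day 35 vs 21 26, genotype by day 21 3.2e+02 (135 higher, 180 lower), genotype by day 35 28, genotype by day 21 to 35 1663, day 35 old 0 and age by day 35 11. With the sex covariate: day 21 KO 1504, WT day 35 vs 21 0, genotype by day 21 602, genotype by day 35 155, genotype by day 21 to 35 1.4e+02 (94 higher, 42 lower) and age by day 35 11. At the counts of 0, edgeR had 1508 (day 35 old, groups compared), 838 (day 35 old, neutrophil covariate) and 938 (WT day 35 vs 21, sex covariate) genes at an unadjusted p under 0.05, and DESeq2 with all libraries called 1572 (day 35 old) and 74 (WT day 35 vs 21), and on day 35 old and WT alone 3.3e+02, 20 lower. Leaving out each library of a comparison in turn gave naive KO 11 to 69, day 21 KO 1358 to 2231, day 35 KO 53 to 453, WT day 21 1727 to 3002, WT day 35 1406 to 2857, WT day 35 vs 21 0 to 13, KO day 21 5475 to 6089, KO day 35 1597 to 3107, KO day 35 vs 21 2590 to 3296, genotype by day 21 514 to 1639, genotype by day 35 7 to 190, genotype by day 21 to 35 123 to 517, naive old 494 to 1409, day 35 old 0 to 2044, old day 35 973 to 3231 and age by day 35 3 to 347.

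Of 232 list calls by camera, 12 held with an estimated correlation, with lists called then numbering naive KO 0, day 21 KO 0, day 35 KO 0, WT day 21 2, WT day 35 0, WT day 35 vs 21 1, KO day 21 2, KO day 35 0, KO day 35 vs 21 3, genotype by day 21 0, genotype by day 35 0, genotype by day 21 to 35 3, naive old 1, day 35 old 0, old day 35 0 and age by day 35 0; fry moved the number for naive KO 0, day 35 KO 11, WT day 35 vs 21 3, KO day 21 19, genotype by day 35 4, genotype by day 21 to 35 8 and age by day 35 0. Without the 3 libraries the naive KO number was 15, and leaving out 1 library gave naive KO 4 to 12 and WT day 35 vs 21 8 to 17. Without the 3 libraries camera turned the homeostatic list of age by day 35 from lower to higher (adjusted p = 9.88e-05). Of 1030 gene results 861 kept their side of the threshold and their direction without a filter and 898 with the sex covariate. Those that lost their call numbered 9 with RLE, 6 with DESeq2, 8 with the stricter filter, 174 with only the groups compared, 75 with the index block, 97 with day 35 WT 3 moved and 95 without the 3 libraries, none turning direction, and 284 with the neutrophil covariate, where 38 turned. Turned among those named were Ngp (log2FC −0.10, day 35 KO), Nusap1 and Ube2c (0.026 and 0.40, WT day 35) and Hp (1.70, WT day 21, and −1.64, day 35 old).

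Without the 3 libraries the overlap of KO and age effects held 19 genes at day 35, where 19 were called for age, and 147 in naive mice. It held 0 to 245 and 7 to 50 without 1 library (0 without day 35 old 1, where the age contrast called 0 genes). That of day 35 KO with naive age held 681 without the 3 and 39 to 263 without 1. Atg7 passed the threshold with only the groups compared for day 21 KO (log2FC 0.48, adjusted p = 0.00455), day 35 KO (0.54, adjusted p = 0.0107), WT day 35 (−0.49, adjusted p = 0.0371) and genotype by day 21 (1.15, adjusted p = 0.0294); with the neutrophil covariate for KO day 21 (1.37, adjusted p = 7.95e-05), KO day 35 (0.92, adjusted p = 0.00331) and old day 35 (0.73, adjusted p = 0.0319); and for KO day 21 with the stricter filter (0.71, adjusted p = 0.0482) and DESeq2 (0.71, adjusted p = 0.0429). Without 1 library its log2FC was KO day 21 0.51 to 1.00, KO day 35 0.49 to 0.98, genotype by day 21 0.95 to 1.45 and day 35 old 0.20 to 1.07.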

Other observations

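This test was chosen only after the results had been seen. KO at day 35, or its EAE severity, and age without EAE may alter the same genes in the same direction. The covariance of their log2FC was 0.093, the highest of 35 divisions of the day 35 libraries (highest other 0.079). It was 0.054 without naive WT 1 and 0.166 without naive WT 3.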
